A study of Mus musculus with 3 samples.

How the data were processed

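Gene expression was measured by stranded mRNA sequencing in RAW 264.7 cells, a mouse macrophage line, after 5 h with lipopolysaccharide (LPS, the bacterial ligand of TLR4) at 100 ng/mL, per the labels' protocols. There were 3 libraries. In 1 library the cells carried a control shRNA, and in 2 libraries they carried shRNAs against GIV (Girdin, gene Ccdc88a), with a different shRNA in each. Groups and shRNA numbers were taken from the sample titles. The labels' source field spells the line name differently from their protocols, and the protocols' name is used here. No library without LPS was analysed here.

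The deposited table holds 1 column per library and 54331 features with versioned Ensembl gene identifiers. Its values are normalized counts made by the authors, treated here as a signal that is never negative. Salmon, DESeq and DESeq2 and the genome build GRCm38 are named in the submitters' processing notes, without versions, settings or roles, and the annotation release is not given in the sources used here. Column totals were 49088771 for the control, 49756670 for the library labelled shRNA 1 and 47349097 for the library labelled shRNA 2. The commonest lowest value was 0.931, 1.11 and 0.966 in that order. Between 82.9% and 83.6% of the low values of a library lay within 0.1 of a whole multiple of that step, too few to recover whole reads, so no count model was fitted. Dividing each total by its step gives roughly 52700000, 44800000 and 49000000 reads. Sampling error is therefore small for abundant genes, whereas a value near 1 stands for about 1 read. Values in the later rows of the table are written to 7 significant digits.

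Identifiers were matched without their version to the GENCODE M21 annotation of GRCm38, which gave names, positions, transcript lengths and GC content. A symbol was found for 54097 identifiers and not for 234. The 13877 features with a mean value of at least 10 were tested. Values were put on the log2(value + 1) scale, and every fold change on this scale understates the change of low genes. The group comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment. Only 1 residual degree of freedom per gene was available, from the pair of libraries labelled GIV-depleted, and the lone control is assumed to vary as they do. Nothing in the labels says that the libraries came from separate experiments, so p-values measure the spread between these libraries and between 2 different shRNAs. For each shRNA alone there is no test, and features were counted by a size rule of at least 2-fold.

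Before the data were examined, 33 gene lists holding 703 different genes were fixed, covering inflammatory, interferon, signalling, metabolic and organelle genes, RNA quality and markers of other cell types. The 30 lists with at least 3 tested genes were tested with limma's camera at a preset correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and camera on ranks were run beside it. With an estimated correlation, camera tests on the 1 residual degree of freedom, so a list could hardly pass and its values decide nothing. This held even for lysosome and autophagy genes, whose estimated correlation of 0.011 lay near the preset 0.01. The median of each list was also placed among 10000 random lists of the same size matched on mean value, as a description of these libraries. Agreement of the 2 shRNAs was set beside 100 simulations of unchanged libraries that share 1 control.

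The genes named were fixed by rule before the data were examined. They are Ccdc88a and its paralogs, the 10 higher and 10 lower features with the largest smaller difference of the 2 shRNAs at a mean value of at least 50, and up to 4 members of each list with the largest mean difference. Also named by that rule are Tnf, Il6, Il1b, Il10, Nos2, Arg1, Ifnb1, Cxcl10, Tlr4, Cd14 and Myd88, and the 3 highest and 3 lowest features for shRNA 2 minus shRNA 1. Other genes named were chosen after their values were seen, and the text says so. Some genes that the rule names are not reported here.

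The fit was tested on simulated data with 2 libraries against 1, over 13877 features with 200 changed. It recovered 2.67% of features changed 2-fold, 43.2% of those changed 4-fold and 62.3% of those changed 8-fold. A mean of 80.6 calls was made per simulation, of which 8.25 were false, a larger share than the nominal 5%. Of 100 simulated lists of 30 genes shifted by 0.3 on the log2 scale, 97 were called, as were 2 of 300 unshifted lists. Simulated genes varied independently and their lists were drawn at random. These shares therefore need not hold for real lists, whose genes may vary together. Alternatives covered the pseudocount, the filter on low values, library scaling, quantile normalization, the variance trend, the fold rule and leaving out each library labelled GIV-depleted. Restricting the features to those above 0 in every library, restricting them to protein-coding genes and removing a GC and length trend were added after the data had been seen. The tests of technical explanations were likewise all chosen after the results they bear on had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.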

Results

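RNA from LPS-stimulated RAW 264.7 macrophages was sequenced in 3 libraries, 1 with a control shRNA and 2 with shRNAs against GIV, a large scaffold and G-protein modulator encoded by Ccdc88a. The series title names dampening of TLR4 signalling and of macrophage inflammatory responses by GIV as its subject. Totals ranged from 47349097 to 49756670 normalized counts per library, and 20030 to 20590 features had a value above 0. There was a single control, so no value of the control has a replicate error.

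Ccdc88a (ENSMUSG00000032740.16, chromosome 11, 29373658 to 29510808, GRCm38) was examined first, as the targeted gene. Its value was 2580 normalized counts in the control, 1734 in the library labelled shRNA 1 and 2561 in the library labelled shRNA 2. The log2 difference from the control was -0.57 for the library labelled shRNA 1 and -0.01 for the library labelled shRNA 2. The library labelled shRNA 2 thus shows no lower Ccdc88a mRNA, which goes against its label at the mRNA level, and protein was not measured in these data. Over both libraries the difference was -0.29 (SE 0.28), with an adjusted p of 0.85 in limma. Under 5 scalings the difference of the library labelled shRNA 2 ranged from -0.21, with a GC and length trend removed, to 0.04, with equal totals. The paralogs Ccdc88b (5740 in the control, 5191 and 5809) and Ccdc88c (224 in the control, 206 and 260) lay close to the control. Every direction given below for both libraries labelled GIV-depleted rests in part on the library labelled shRNA 2.

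**Figure D1:**
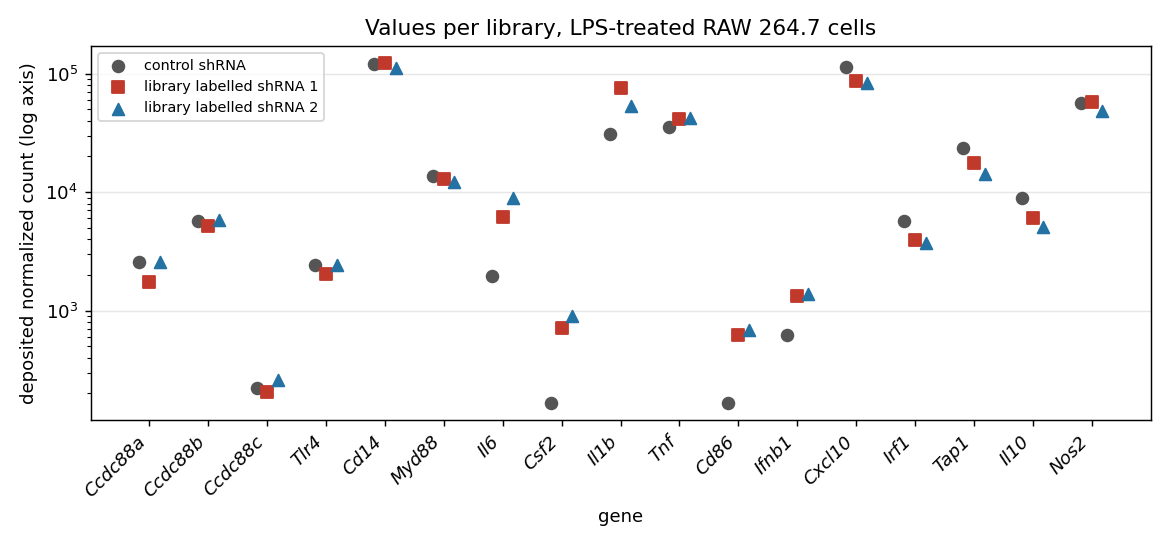
Deposited normalized counts (log axis) of 17 genes in the control library (circles), the library labelled shRNA 1 (squares) and the library labelled shRNA 2 (triangles), 1 point per library and no error bars. Ccdc88a is at 2580, 1734 and 2561, while Il6 is at 1957, 6114 and 8985.

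The comparison of the libraries labelled GIV-depleted with the control asks how transcripts of LPS-treated macrophages differ between cells given shRNAs against GIV and cells given a control shRNA. Lower Ccdc88a mRNA was seen in 1 of these 2 libraries, that labelled shRNA 1. That log2 difference of -0.57 is between single libraries and has no test. In the library labelled shRNA 1, 2314 of the 13877 features differed from the control by at least 1.5-fold. Transcripts of several inflammatory cytokines had higher values in both libraries labelled GIV-depleted, while interferon-response, lysosomal and macrophage-identity transcripts tended to lower values. Il6, a secreted cytokine of the acute response, had 1957 normalized counts in the control, 6114 in the library labelled shRNA 1 and 8985 in the library labelled shRNA 2. Csf2, which encodes GM-CSF, had 166, 714 and 899. No single gene passed an adjusted p of 0.05 in limma, the lowest being 0.055, and 963 of the 13877 features had an unadjusted p under 0.05 where 694 are expected by chance. Of these 963, 627 were higher and 336 lower, a balance that turned round without a filter on low values, with 1012 higher and 1704 lower. In simulated data of this design, with 200 changed features, the same fit recovered 43.2% of 4-fold changes, and 2.67% of 2-fold changes. A mean of 80.6 calls was made there against 0 here. Fewer or smaller changes in the real data, or lower recovery, could each give this, and which holds was not tested. Single genes are therefore given by their values.

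As a group, the proinflammatory cytokines rose relative to other genes, with 12 of 17 tested members higher in both libraries labelled GIV-depleted and 4 lower in both. Their median log2 difference was 0.24 and limma's camera gave an adjusted p of 0.0087 over 30 lists. The adjusted p was 0.97 with an estimated correlation, 0.063 on ranks and 0.076 without a filter on low values. The list was also called, as higher, when the library labelled shRNA 1 was set apart from the other 2 (adjusted p = 0.0068, and 0.81 with an estimated correlation). Adjusted over the list alone, 2 genes passed in limma, against 0 over all genes. These were Il6, with a log2 difference of 1.92 (SE 0.27), and Csf2, with 2.26 (SE 0.24). Il1b, the precursor of interleukin-1 beta, had 31161, 75964 and 52880 normalized counts in the control and the libraries labelled shRNA 1 and shRNA 2. Il12b had 1.87, 14.5 and 28.8, which is near the detection floor in the control. Tnf had 35124, 41171 and 41924, a difference of 0.24 (SE 0.13). Tnfsf15 was high in 1 library only, with 173, 2083 and 185.

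The chemokine list did not pass (adjusted p = 0.46), with 6 of 18 members higher in both libraries and 4 lower in both. Its members with the largest differences were Cx3cl1 (34.3, 196 and 110 normalized counts), Ccl17 (105, 270 and 204), Ccl22 (9279, 26578 and 14730) and Cxcl2 (11279, 25465 and 19893). Among classically activated macrophage genes (adjusted p = 0.71), Cd86, a T-cell costimulatory ligand, had 168, 623 and 688. It was the 1 gene of that list to pass when adjusted over the list alone. Nos2, the inducible nitric oxide synthase, had 56568, 57600 and 48294. The anti-inflammatory list fell as a group, with a median of -0.27, 10 of 18 members lower in both libraries and 4 higher in both (camera adjusted p = 0.047). That call was lost on ranks (adjusted p = 0.12), with quantile normalization (0.062), without the variance trend (0.20) and without a filter (0.24). With an estimated correlation camera gave this list an adjusted p of 0.97. Il10 had 8907, 6047 and 5109 normalized counts, and Klf4, a transcription factor, had 619, 374 and 388. Higher in both libraries were Ccl24, with 5.02, 5.60 and 20.3, and Clec10a, with 54.5, 85.7 and 91.1. Arg1 was under the filter, with 5.67, 2.03 and 7.82.

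Genes of the TLR pathway itself showed no shared direction. In the TLR signalling list 13 of 36 members were higher in both libraries and 16 lower in both (adjusted p = 0.96). Tlr4 had 2440 normalized counts in the control, 2023 in the library labelled shRNA 1 and 2412 in the library labelled shRNA 2. The adaptor Myd88 had 13555, 12978 and 12128. Cd14, the LPS co-receptor, had 119577, 122965 and 112411, and its small mean difference of -0.02 turned positive under quantile normalization (0.11) and with the GC and length trend removed (0.06). The list of NF-kB subunits and feedback inhibitors did not pass either (adjusted p = 0.98). Within it Cish had 245, 762 and 575, whereas Socs1, another inhibitor of cytokine signalling, had 514, 290 and 236.

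The interferon-response list fell as a group, with 32 of 44 members lower in both libraries labelled GIV-depleted. Its median difference was -0.25 (camera adjusted p = 1.3e-05). With an estimated correlation camera gave an adjusted p of 0.97, but that test could hardly call any list here. Median differences were -0.11 for the library labelled shRNA 1 and -0.38 for the library labelled shRNA 2, the larger being that of the library whose Ccdc88a was at the control's level. When the library labelled shRNA 2 was instead set apart from the other 2 libraries, camera with the preset correlation also called the list, lower in that library (adjusted p = 8.1e-18, and 0.93 with an estimated correlation). With the library labelled shRNA 1 set apart, the list was called as higher in that library (adjusted p = 0.044, and 0.87 with an estimated correlation). Irf1, a transcription factor of the interferon response, had 5652, 3925 and 3718 normalized counts. Iigp1 had 5437, 4297 and 3275, and Cxcl10, an interferon-induced chemokine, had 113956, 87117 and 82837. The 1 member higher in both libraries was Ifnb1, which encodes interferon beta, with 620, 1338 and 1385.

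The antigen-presentation list also fell, with 13 of 18 members lower in both libraries and a median of -0.24 (camera adjusted p = 0.0037, and 0.97 with an estimated correlation). Its mean was positive, at 0.03, and its members with the largest positive differences were the class II genes H2-Aa (1.97, 16.5 and 75.5 normalized counts) and H2-Eb1 (3.77, 9.01 and 27.4). Tap1, a peptide transporter of the class I pathway, had 23768, 17564 and 14131, and H2-Q4 had 13227, 9979 and 7529. The call ended with the GC and length trend removed (adjusted p = 0.058, median -0.19) and without a filter on low values (0.29). Set apart from the other 2, the library labelled shRNA 2, with Ccdc88a at the control's level, was lower in this list (adjusted p = 0.00018, and 0.93 with an estimated correlation).

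Lysosome and autophagy genes fell as a group, with 19 of 28 members lower in both libraries, 2 higher in both and a median of -0.21 (camera adjusted p = 0.00033, and 0.97 with an estimated correlation). The cathepsins Ctsd and Ctsl had 77016 and 43533 normalized counts in the control, 55025 and 33255 in the library labelled shRNA 1, and 56244 and 27314 in the library labelled shRNA 2. Gpnmb, the member with the largest difference, went the other way, with 4815, 5114 and 10145. When the library labelled shRNA 1 was set apart from the other 2, the list was called as lower in it (adjusted p = 0.029, and 0.81 with an estimated correlation). Macrophage identity genes fell as well, with 15 of 22 lower in both libraries and a median of -0.18 (camera adjusted p = 0.0068, and 0.97 with an estimated correlation). Lyz2 had 199781, 121997 and 138145 normalized counts, and Csf1r, the M-CSF receptor, had 18776, 9476 and 15612, whereas Cd33 had 136, 162 and 316. The macrophage identity call ended with the GC and length trend removed (adjusted p = 0.054, median -0.07) and without a filter on low values (0.078). Setting the library labelled shRNA 1 apart also called this list, as lower (adjusted p = 0.029, and 0.81 with an estimated correlation). Phagocytosis and scavenger receptor genes fell too, with 12 of 20 lower in both libraries and a median of -0.26 (camera adjusted p = 0.025, and 0.97 with an estimated correlation). That list shares 5 tested genes with macrophage identity and 4 with the anti-inflammatory list, and without these its remaining 11 genes gave 0.081. It was also lost without the variance trend (0.081) and without a filter on low values (0.23). With the library labelled shRNA 1 apart it was called as lower at a smaller adjusted p than for the grouping (0.0016, and 0.81 with an estimated correlation). Fcgr1, an Fc receptor, had 48715, 32239 and 33167 normalized counts, whereas Fcgr2b had 2724, 2744 and 5053.

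The control library also stood apart in measures of the RNA. Mitochondrially encoded transcripts made up 1.43% of the control's total, 0.995% in the library labelled shRNA 1 and 1.14% in the library labelled shRNA 2. As a list they fell, with 12 of 15 lower in both libraries and a median of -0.49 (camera adjusted p = 2.0e-05, and 0.97 with an estimated correlation). The library labelled shRNA 1, set apart from the other 2, was lower in this list as well (adjusted p = 0.00020, and 0.81 with an estimated correlation). Among 11568 protein-coding genes above 0 in every library, longer transcripts had higher values in both libraries relative to the control. The Spearman correlation across genes of the difference with length was 0.21 for the library labelled shRNA 1 and 0.20 for the library labelled shRNA 2, against -0.01 between those libraries. With GC content it was -0.25, -0.19 and 0.08 in that order, genes not being independent replicates. The nuclear RNA Neat1 had 22586, 12486 and 13729 normalized counts and passed when adjusted over its list alone, whereas Malat1 had 9410, 11121 and 12513. That list as a whole did not pass (adjusted p = 0.90). These shifts ran alongside every list that passed.

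**Figure D2:**
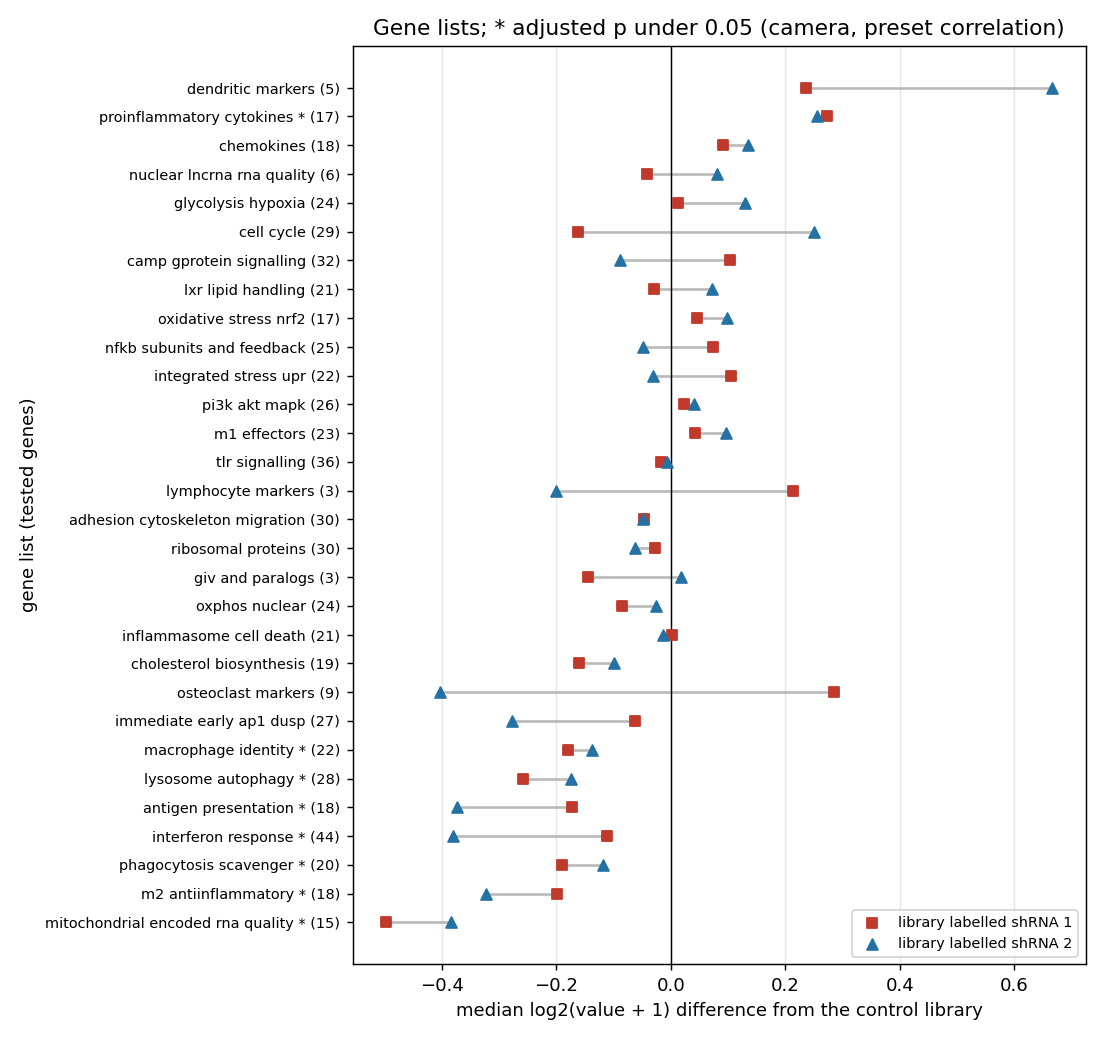
Median log2(value + 1) difference from the control library for 30 gene lists, in the library labelled shRNA 1 (squares) and the library labelled shRNA 2 (triangles), with tested genes in brackets. Asterisks mark the 8 lists with an adjusted p under 0.05 in camera with the preset correlation. With an estimated correlation 0 passed, but with 1 residual degree of freedom hardly any list could. The interferon-response medians are -0.11 and -0.38.

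The remaining lists did not pass in camera. Metabolic and organelle lists gave an adjusted p of 0.11 for cholesterol biosynthesis, 0.18 for nuclear-encoded oxidative phosphorylation, 0.46 for glycolysis and hypoxia, 0.46 for the oxidative stress response, 0.96 for lipid handling and 0.36 for ribosomal proteins. Signalling and stress lists gave 0.42 for immediate-early genes, 0.83 for inflammasome and cell death, 0.85 for the integrated stress response, 0.87 for PI3K, AKT and MAPK genes and 0.98 for cAMP and G-protein signalling. The adhesion and migration list gave 0.42, and GIV with its paralogs 0.71. Cell cycle genes (0.51) and osteoclast markers (0.42) did not pass either. Markers of other cell types gave 0.51 for dendritic cells and 0.98 for lymphocytes. Too few fibroblast (2 of 12), neutrophil and mast cell (2 of 12) and epithelial (0 of 11) markers passed the filter on low values to be tested. Batf, a transcription factor in the immediate-early list, had 0.93 normalized counts in the control, about 1 read, against 339 and 578, and passed when adjusted over that list alone.

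By the rule of at least 2-fold, 960 features differed from the control in the library labelled shRNA 1, of which 552 were higher and 408 lower. In the library labelled shRNA 2 there were 1016, of which 664 were higher and 352 lower. The 2 libraries differed from each other by this rule in 865 features. In both libraries 321 features were higher and 128 lower, and 19 went in opposite directions. The balance depended on the filter, with 1077 higher and 1031 lower without one and 140 higher and 30 lower at a mean value of at least 50. Unchanged libraries that share 1 control gave 179 higher and 179 lower in simulation, and independent lists would share 26.4 and 10.3. Pearson's r of the differences across features was 0.65, against 0.50 simulated, and the covariance was 0.39, against 0.21 simulated, a difference of 0.18. For the 13733 features above 0 in every library, r was 0.59 against 0.50 simulated, and the covariance was 0.18 against 0.13, a difference of 0.053, so the 144 features listed at 0 carried most of the excess. With 1 control library the control cannot be split, so part of this excess may come from the shared control.

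**Figure D3:**
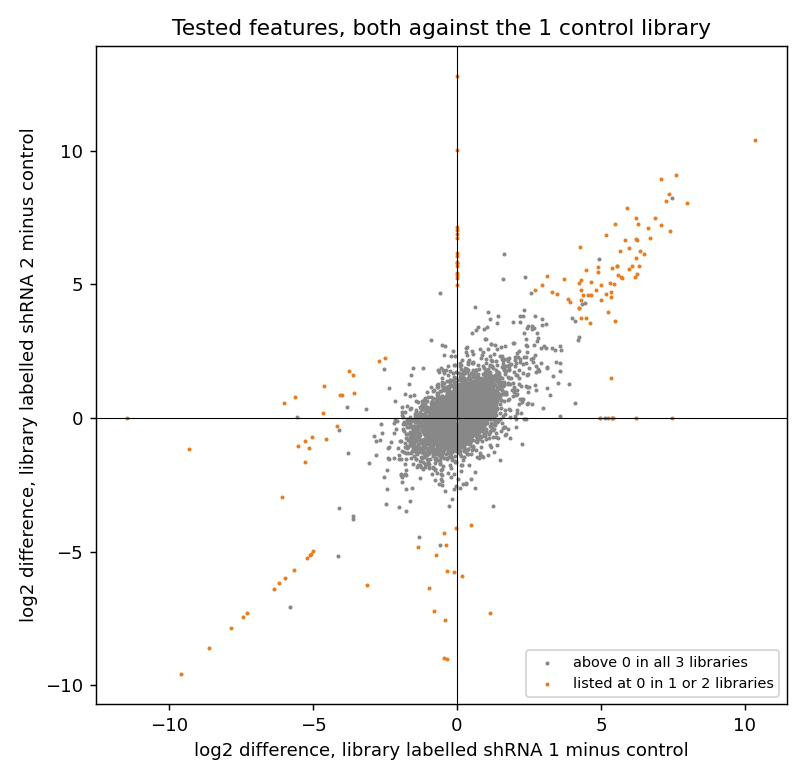
Log2(value + 1) difference from the control of each of 13877 tested features, in the library labelled shRNA 1 (x axis) and the library labelled shRNA 2 (y axis). Orange points are the 144 features listed at 0 in 1 or 2 libraries, among them Gm10443 at 10.36 and 10.42, and grey points are above 0 in all 3.

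The features with the largest differences by the fixed rule were mostly pseudogenes listed at 0 in 1 group, and values of such near-identical copies are uncertain. Gm10443, a processed pseudogene (chromosome 6, 86334031 to 86334240), was listed at 0 in the control and had 1313 and 1367 normalized counts in the libraries labelled shRNA 1 and shRNA 2. Gm10175 had 766 in the control and was listed at 0 in both others. Of the 449 features that differed 2-fold in the same direction, 91 were listed at 0 in at least 1 library, while 207 higher and 62 lower ones were protein coding and above 0 throughout. Il17rc, a receptor subunit for interleukin 17, had 1909, 351 and 302 normalized counts, a log2 difference of -2.55 (SE 0.21) and an adjusted p of 0.16 in limma. Kank3 had 124, 32.5 and 26.3, and Lims2 had 350, 102 and 30.2. Among protein-coding genes named after their values were seen, Slc40a1, the iron exporter ferroportin, had 2.98, 80.8 and 75.7, and Col18a1 had 690, 170 and 267.

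Between the 2 libraries labelled GIV-depleted there was 1 library per shRNA and hence no test. The median cell cycle difference from the control was -0.16 in the library labelled shRNA 1 and 0.25 in the library labelled shRNA 2. The difference between these libraries was higher than in all 10000 matched random lists. The cell cycle list was not alone in this. The mitochondrially encoded list also lay at percentile 100, and the interferon-response, osteoclast, immediate-early and integrated stress lists lay at percentile 0. Random lists do not mimic genes that vary together, so these percentiles only describe the libraries. Osteoclast markers had medians of 0.29 and -0.40, with Dcstamp, a fusion protein of osteoclasts, at 718, 1672 and 550 normalized counts. Immediate-early genes had medians of -0.06 and -0.28. The fixed rule for this contrast returned features listed at 0 in at least 1 library, among them Gm12918 (0, 0 and 7131). Another was the Nnt entry ENSMUSG00000116207.1 (516, 405 and 0), values that hold for that identifier alone. Among genes above 0 throughout, named after their values were seen, Nedd9 had 3.08, 11.8 and 287, and Nckipsd had 966, 106 and 1228.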

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

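Alternatives that restrict the features to those above 0 or to protein-coding genes, and those that remove a GC and length trend, were chosen after seeing the data. The count of 0 genes past the threshold in limma became 1 at an adjusted p under 0.1, at a mean value of at least 50, with equal totals and with TMM factors, and 4 with the GC and length trend removed. It stayed at 0 in the other alternatives, and 963 features had an unadjusted p under 0.05. Without either library labelled GIV-depleted no residual degree of freedom is left, so that count has no value there. The planned edgeR and DESeq2 fits were not run because whole reads could not be recovered. No paired analysis was possible because there is only 1 control library. The 449 features 2-fold apart in both libraries became 1098 at 1.5-fold, 153 at 4-fold, 268 with a pseudocount of 10, 2108 without a filter, 170 at a mean value of at least 50 and 292 for protein-coding genes only. With 1 library labelled GIV-depleted left out, the rule gave 960 to 1016. The 960 of the library labelled shRNA 1 became 2314 at 1.5-fold, 593 with a pseudocount of 10, 5419 without a filter, 382 at a mean of at least 50 and 611 for protein-coding genes. The 1016 of the library labelled shRNA 2 became 2384, 677, 4344 and 424 under the first 4 of these. Pearson's r of 0.65 became 0.66 with a pseudocount of 0.5, 0.61 with one of 10, 0.55 without a filter, 0.67 at a mean of at least 50, 0.59 for features above 0 and 0.60 for protein-coding genes, and Spearman's rho was 0.53. The 8 gene lists called became 3 without a filter. They became 0 with an estimated correlation, where 1 residual degree of freedom let hardly any list pass. For each library labelled GIV-depleted alone, 13 of the 30 lists lay in the outer 2.5% at either end of the matched random lists. That is far more than random lists would place there, so an extreme percentile by itself sets no list apart. The Ccdc88a difference ranged from -0.57 to -0.01 with 1 library left out. Of 2246 alternatives for 177 named genes, 2226 were counted as kept, 6 came past the threshold, 10 moved and 4 reversed. Where 1 library labelled GIV-depleted was left out there was no test, and direction was not compared. Those values were judged by distance from the mean of 2 values, which lies within their SD by construction, rounding apart. The 172 kept and 5 moved for each library left out were thus fixed in advance. Tlr8, for one, went from -0.64 over both libraries to 0.46 in the library labelled shRNA 2. In the other alternatives kept means the same direction and side of the threshold. Reversed there were Ccdc88b (0.10), Cd14 (0.062) and Kcnq1ot1 (-0.21) with the GC and length trend removed, and Cd14 (0.11) with quantile normalization. A filter leaves fewer or more features by construction, and an estimated correlation leaves camera 1 residual degree of freedom. The cause of the other changes was not tested. Depth limits low genes most, since a value near 1 is about 1 read.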

Other observations

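Every test of an explanation below was chosen after the result it bears on had been seen. Within the antigen-presentation list, 14 genes of the class I pathway and 4 of class II were separated after their values were seen. Of the class I genes 13 were lower in both libraries labelled GIV-depleted, with a median of -0.42, while 3 of the class II genes were higher in both, with a median of 0.95 that rests on low values. Families sharing a symbol stem were also examined after the data had been seen, 189 in all. The 11 proteasome beta subunit genes (stem Psmb) were all lower in both libraries, with a median of -0.20 and a camera adjusted p of 0.024. Psmb8, Psmb9 and Psmb10 belong both to this family and to the class I genes above, so the 2 observations overlap. Of 32 centrosomal protein genes (stem Cep), 18 were higher in both and 0 lower in both, with a median of 0.13 and an adjusted p of 0.022. With an estimated correlation the adjusted p was 0.99 for both families. With the GC and length trend removed, camera with the preset correlation gave 0.16 for Psmb, whose median went from -0.20 to -0.12. It gave 0.087 for Cep, whose median did not shrink, going from 0.13 to 0.15.

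The interferon-response and antigen-presentation lists were lower in both libraries labelled GIV-depleted while Ifnb1 and Il6 were higher. An abundance trend is argued against, because the higher of the 2 lists' percentiles among random lists matched on mean value was 0.1. A GC or length trend as the whole cause is argued against for the interferon list, whose adjusted p was 1.1e-06 and median -0.22 after that trend was removed, against -0.25 before. Most of what remained lay in the library labelled shRNA 2, whose Ccdc88a was at the control's level. Its median went from -0.38 to -0.37 (percentile 0 of matched random lists), and that of the library labelled shRNA 1 from -0.11 to -0.07 (percentile 0.06). For the antigen-presentation list the same removal gave 0.058, the median going from -0.24 (SD 1.05 across genes) to -0.19 (SD 1.02). Its mean went from 0.03 to 0.12, and why the call ended was not tested. For that list the trend cannot be told apart from the grouping, since the median kept its sign and the list did not pass. A control library that differs for reasons other than GIV stays open for both, since there is 1 control and its mitochondrially encoded transcripts differed as well (median -0.49).

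Ccdc88a in the library labelled shRNA 2 lay at the control's level. Whether that library is a second control cannot be told apart from depletion here. The covariance of the 2 libraries' differences from the control exceeded, by 0.18, the variance that their difference from each other implies for 1 library, and by 0.053 for features above 0. With 3 libraries such an excess arises whenever the control is by chance the library farthest from the others, so it decides nothing. An shRNA that lowers GIV protein without lowering the mRNA is a biological explanation that was not tested here.

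Features listed at 0 in 1 or 2 libraries lead the largest differences. A candidate explanation is that estimated reads moved between near-identical gene copies. Pseudogenes made up 56.25% of these features, against 9.92% of other features matched on mean value, as that explanation needs. Features listed at 0 in 1 library with at least 50 in both others numbered 24 for the control, 3 for the library labelled shRNA 1 and 6 for the library labelled shRNA 2. Features with at least 50 in 1 library and listed at 0 in both others numbered 9, 2 and 11 in that order, so the control was not the highest there. No biological explanation was tested for this pattern.

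Only 3 splits of the libraries into 1 and 2 exist, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 963 features and the highest other 596, so 1 of the 3 splits gave as many. For gene lists the order differed: the real split called 8, the split with the library labelled shRNA 1 apart called 11 and that with the library labelled shRNA 2 apart called 7, so 2 of the 3 splits called at least 8. Between 7 and 11 lists were thus called whichever library was set apart. With an estimated correlation 0 of these lists passed, but with 1 residual degree of freedom hardly any list could, so that decides nothing.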
